A study of Mus musculus with 6 samples.

How the data were processed

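Gene expression was measured in hepatic stellate cells of mice with cirrhosis induced by carbon tetrachloride, on 3 single-colour arrays of wild-type and 3 of Sept4 knockout samples; the labels do not say whether these are separate mice, pools or repeat hybridisations. The values are deposited as a table of log2 signals for 23473 probes with a value on all 6 arrays. The log base is not stated and was taken from the range of the values. Per the labels, the values had been quantile normalised, total RNA had been extracted with phenol and chloroform, and Cy5 was the dye. Quantile normalisation makes all arrays share 1 distribution, but only the medians were equal here: the mean upper quartile was 7.72 in wild-type and 7.82 in knockout arrays, and the mean highest value 15.7 and 16.7. Between 4.00% and 5.35% of the probes on an array were tied at its lowest value, so a level there is only a bound. The labelling protocol names a microRNA kit and tumour samples, which differs from the stated design of messenger RNA in stellate cells, and the design was taken from the cell type and genotype labels. The background correction and the scanner software are not given in the sources used here. No columns were left unused.

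Probes were named from the platform annotation: 16631 had 1 symbol, 6842 had none and 0 had several. Of 16446 different symbols, 16384 matched a current symbol in a mouse gene table on assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. Symbols are printed as annotated, and some are old. No probe is named Sept4 in that annotation, so the deleted gene was not analysed here. For a gene with several probes, the probe with the highest mean over all 6 arrays gave the gene's value in lists. Of 174 such genes, 24 had probes that passed in opposite directions.

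Differences are knockout minus wild type, fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, without normalising again, with two-sided tests and Benjamini-Hochberg adjustment over all probes. The threshold was an adjusted p of 0.05. The residual degrees of freedom were 4 and the prior added 1.11. Dkk2 was also tested by exact permutation. For a gene at the lowest value on all 3 arrays of a genotype, the fold difference of the group means is given, and that genotype's level is only a bound.

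Before the data were examined, 25 pathway lists and 11 cell type lists were fixed, with 781 members in all, of which 698 were measured. Lists of at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists tested. The genes named in the text followed a rule also fixed then. It took Sept4 and Dkk2, the 12 largest rises and the 12 largest falls among probes with 1 symbol that passed the threshold and whose groups did not overlap, and up to 6 members per list by size of difference among those that passed, or otherwise the 3 with the smallest p. Clone names were passed over. Of the alternatives, most were fixed then too: quantile normalisation, median centring, leaving out the dimmest 25% or 50% of probes, a linear offset at the 10th percentile, a trended and robust variance prior, array weights, the replicate number as a block, leaving out each array, the mean of a gene's probes, an estimated correlation, fry, and an ordinary test per probe with equal variances. Cyclic loess and leaving out probes at an array's lowest value were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

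The fit was tested on simulated data with known answers, in 10 simulations over 23473 probes with 200 changed in each. It recovered 25.9% of changes of 0.5 on the log2 scale, 54.6% of changes of 1 and 68.9% of changes of 2, and 6.42% of the calls were false. The same simulations called a shifted list in 10 of 10 and 0 of 350 unshifted lists. Noise was drawn independently for each probe, so the genes of a list were uncorrelated. The lists called in the data had estimated correlations of 0.302 to 0.392, so the simulations do not test camera under such correlation. With 200 of 23473 probes changed, against 42.7% that passed in the data, the recovery rates need not hold for the data.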

Results

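Messenger RNA was profiled on single-colour microarrays in hepatic stellate cells, the vitamin A-storing pericytes of the liver that make most of its collagen when they become myofibroblasts. The cells came from mice in which carbon tetrachloride, a hepatotoxin, had produced cirrhosis. There were 6 arrays, 3 from wild-type mice and 3 from mice lacking Sept4, which encodes a septin, a filament-forming GTP-binding protein. Each array gave a normalised log2 signal for 23473 probes, of which 16631 carried 1 gene symbol. The array medians were all 5.02, and between 940 and 1255 probes on each array lay at that array's lowest value. Pearson correlations across probes were 0.986 between wild-type arrays, 0.981 to 0.982 between knockout arrays and 0.967 to 0.971 between the genotypes. The number of arrays limits the precision of every difference below. Nothing shows whether the arrays came from separate cell isolations, so the p-values measure the spread between these samples, which may be technical. The lowest and highest values of the arrays also separated the genotypes, with a mean highest value of 15.7 in wild-type and 16.7 in knockout arrays. Whether both genotypes were processed together is not known here. If they were not, processing coincides with genotype, and the differences below cannot be assigned to the loss of Sept4 alone.

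The comparison of the genotypes asks how the loss of Sept4 changes gene expression in stellate cells of the cirrhotic liver, and the title of the series names the Wnt antagonist Dkk2 as lower without Sept4. Dkk2, a secreted protein that blocks Wnt co-receptors, had a mean log2 signal of 4.79 ± 0.02 (SD, n = 3) in wild-type cells and 0.82 ± 0.43 (SD, n = 3) in knockout cells. The log2 difference was -3.97 ± 0.23 (SE), with an adjusted p of 0.000526 in limma. The knockout signal is near the lowest values of the arrays, so the size of the fall is imprecise, and with a linear offset added it was -2.86. The wild-type arrays read 4.79, 4.80 and 4.77, and the knockout arrays 1.01, 1.13 and 0.32, the last of them at the lowest value of its array. An exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 can give. Dkk2 was measured by 1 probe. The title of the series already names its fall, which may have been found on these samples, so its fall here is not independent evidence. Sept4 itself is not named among the probes used and was not analysed here, so the genotype labels were not checked by the deleted gene.

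Apart from Dkk2, the 12 largest falls in knockout cells included Ptgs2, Ivl, Acta1 and Tll1. Ptgs2, which encodes cyclooxygenase 2, fell from 10.86 ± 0.04 to 7.88 ± 0.12 (SD, n = 3), a log2 difference of -2.98 ± 0.08 (SE). The long pentraxin Ptx3 fell by 2.72 on the log2 scale. Involucrin (Ivl), a protein of the cornified cell envelope, differed by -3.29, and Sprrl9, of the small proline-rich family, by -2.89. The skeletal muscle actin Acta1 and the tolloid-like metalloprotease Tll1 each differed by -2.97. Ahrr, the repressor of the aryl hydrocarbon receptor, differed by -2.87, the dim latrophilin Lphn3 by -2.64 (-1.58 with the linear offset) and the histone gene Hist1h2ba by -2.63. The potassium channel gene Kcnj5 lay at the lowest value on all 3 knockout arrays, and its group mean there was 7.21-fold lower. The 95% confidence interval of its log2 difference was -3.83 to -1.87, and with the linear offset the difference was -1.68. For the chromatin remodeller gene Chd8, 1 probe fell by 2.82, whereas its other, brighter probe differed by only -0.27 with an adjusted p of 0.0125. Of these dim genes, Lphn3 lay at the lowest value on 2 knockout arrays and Chd8 on 1. Ahrr and Hist1h2ba were also dim in the knockout, with means of 1.90 and 1.41, so the sizes of their falls are imprecise.

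The 12 largest rises included the acute-phase gene Saa3, Cuedc1 and the dim gene Nfat5, the transcription factor of the response to osmotic stress. Nfat5 differed by 3.76 ± 0.41 (SE) on the log2 scale, and by 2.65 with the linear offset. Saa3 rose from 3.81 ± 0.21 to 7.29 ± 0.15 (SD, n = 3), or 11.2-fold. Cuedc1 rose by 3.28 and the orphan receptor gene Gpr160 by 3.23. Akp2, the tissue-nonspecific alkaline phosphatase, rose from 7.74 ± 0.05 to 10.9 ± 0.07 (SD, n = 3), an 8.74-fold difference. The lipid droplet gene Cidea rose by 2.96, the oxysterol-binding protein relative Osbpl5 by 2.84, the steroid sulfate transporter Slc10a6 by 3.07 and the steroid-converting enzyme Hsd3b2 by 2.97. Gpr103 lay at the lowest value on all 3 wild-type arrays, and its group mean was 9.12-fold higher in the knockout. The 95% confidence interval of its log2 difference was 2.88 to 3.50, and with the linear offset the difference was 1.84. The secreted C1q-family gene C1qtnf3 rose by 2.89 (1.91 with the linear offset) and the vomeronasal receptor gene V1ri10 by 2.88. Slc10a6, Hsd3b2 and V1ri10 were dim, with wild-type means of 1.08, 1.05 and 1.17, so the sizes of their rises are imprecise. Nfat5, Slc10a6 and C1qtnf3 each lay at the lowest value on 1 wild-type array, and the adjusted p-values of the 24 genes ranked by size ran up to 0.0116.

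**Figure D1:**
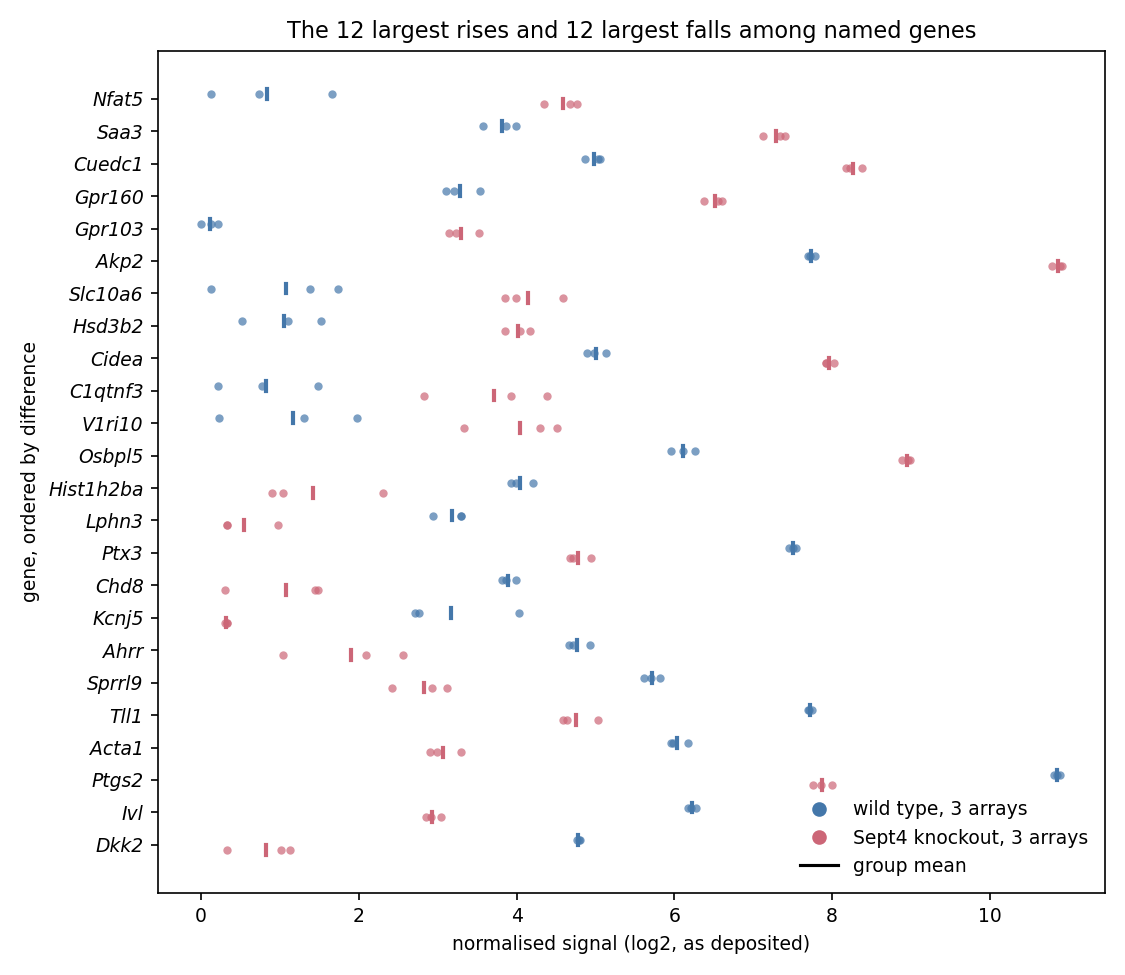
Normalised log2 signal (horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls, ordered by difference (vertical axis); points are single arrays, 3 per genotype, and vertical bars are group means. The rule that picked these genes required that the arrays of the 2 genotypes do not overlap. Dkk2 reads 4.77 to 4.80 in wild-type cells and 0.32 to 1.13 in knockout cells.

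Across all probes, 10025 of 23473 (42.7%) passed an adjusted p of 0.05 in limma. Of these, 6271 were higher in the knockout and 3754 lower, so 62.6% were higher. At least a 2-fold difference was also seen in 1647 of them, 879 higher and 768 lower. Among probes with 1 symbol, 7357 passed, 4879 higher and 2478 lower. At an unadjusted p under 0.05 and at least 2-fold, there were 2006 probes, 1099 higher and 907 lower. For that count the majority turned to lower after quantile normalisation, with 856 higher and 1067 lower, after cyclic loess, with 837 and 1105, and without the dimmest 25% of probes, with 464 and 589. It was also narrowly lower with the linear offset, with 568 and 571, and without probes at an array's lowest value, with 708 and 724. The 3 values of one genotype lay wholly above those of the other for 13183 probes (56.2%), where chance gives 10%. The share of calls that were higher depended on scaling. Quantile normalisation of the deposited values gave 9986 calls, 52.5% of them higher, and cyclic loess, chosen after the data were seen, gave 10003 with 51.5% higher. The median difference of all probes was 0.12 as deposited, 0.02 after quantile normalisation and 0.01 after cyclic loess, so small differences are best read against that shift.

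Genes that mark activated stellate cells and myofibroblasts were mostly lower in the knockout. The title of the series ties Sept4 loss to a myofibroblastic change, and the direction of this list's median is the opposite. All arrays are of cells from cirrhotic mice, so they compare the genotypes after injury and do not follow such a change over time. Of 22 measured genes, 15 fell and 5 rose. Tagln, which encodes the smooth muscle protein transgelin, fell from 13.19 ± 0.05 to 10.74 ± 0.05 (SD, n = 3), or 5.47-fold. The surface glycoprotein gene Thy1 fell by 2.24, the metalloproteinase inhibitor gene Timp1 by 1.52 and osteopontin (Spp1) by 1.26. Acta2, the smooth muscle actin by which these cells are usually recognised, fell by 0.56 ± 0.08 (SE), and is named here after its value was seen. After quantile normalisation Acta2 fell by 0.93. In the opposite direction, Col3a1 rose by 2.09 and Thbs2, which encodes thrombospondin 2, by 1.46. The remaining rises were Vim by 0.61, Col1a1 by 0.45 and Pdgfrb by 0.30, named here after their values were seen. After quantile normalisation these 3 rose by 0.15, 0.28 and 0.14. The median log2 difference of the list was -0.49, with an adjusted p of 0.000252 in camera, limma's test of a list against all other genes at a preset correlation. The call was lost with an adjusted p = 0.752 with an estimated correlation. Adjusted over the list alone, 15 genes fell and 5 rose as well.

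Markers of quiescent stellate cells moved mostly the other way, although the list as a whole did not pass. Of 19 measured genes, 9 rose and 3 fell, and adjusted over the list alone 10 rose and 3 fell. Lrat, the enzyme that esterifies retinol for storage, rose from 5.05 ± 0.30 to 7.46 ± 0.04 (SD, n = 3), or 5.31-fold. Cygb, which encodes cytoglobin, rose by 2.05, the collectin gene Colec11 by 1.44, Ifitm1 by 1.03, Rgs5 by 0.99 and hepatocyte growth factor (Hgf) by 0.93. The 3 that fell were Pparg by 0.56, desmin (Des) by 0.41 and nestin (Nes) by 0.30, named here after their values were seen. The list median was 0.61, with an adjusted p of 0.128 in camera. Among 23 retinoid and lipid droplet genes, 8 rose and 3 fell, the same numbers as adjusted over the list alone. The retinol dehydrogenase gene Rdh10 rose by 1.16 and the retinaldehyde dehydrogenase gene Aldh1a3 by 0.88, whereas the retinol transporter Stra6 fell by 1.05 and the receptor gene Rarg by 1.09. That list had a median of 0.12 and an adjusted p of 0.775.

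Collagen genes did not move together. Of 15 measured, 9 rose and 3 fell, with the same counts adjusted over the list alone. Col3a1 rose from 12.13 ± 0.07 to 14.22 ± 0.05 (SD, n = 3), or 4.26-fold, and Col6a1 rose by 1.21, whereas Col1a2, a chain of type I collagen, fell by 1.20. Col1a1, the other chain of type I collagen, rose by 0.45 with an adjusted p of 0.00309 in limma, and is named here after its value was seen. After quantile normalisation Col1a1 rose by 0.28. Among 24 genes of the other matrix proteins and crosslinking enzymes, 6 rose and 8 fell, also when adjusted over the list alone. Emilin1 rose by 1.49, lumican (Lum) by 1.24 and decorin (Dcn) by 0.91, whereas the crosslinking enzyme Lox fell by 0.98 and tenascin C (Tnc) by 0.94. Matrix proteases and their inhibitors also moved both ways, with 10 of 25 higher and 8 lower, and 10 higher and 9 lower adjusted over the list alone. Stromelysin 1 (Mmp3) rose by 1.32, gelatinase A (Mmp2) by 1.21 and the dim gelatinase B gene Mmp9 by 1.59 (0.82 with the linear offset), whereas Mmp8 fell by 1.75 and the urokinase receptor gene Plaur by 1.23. The medians were 0.32, -0.03 and 0.05, with adjusted p-values of 0.407, 0.400 and 0.681 in camera. The median of the protease list turned to -0.02 after either scaling.

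Genes of transforming growth factor beta and bone morphogenetic protein signalling moved in both directions, and so did the ligand genes among them. Of 27 measured, 14 rose and 6 fell, and so they did adjusted over the list alone. Tgfbi, a secreted matrix protein induced by the pathway, rose by 1.58 ± 0.09 (SE), and Id3, a target of bone morphogenetic proteins, by 1.47 ± 0.06 (SE). The ligand genes Tgfb3 and Inhba fell by 1.21 and 0.83, and the activin antagonist Fst fell by 0.79. The ligand genes Tgfb1 and Tgfb2 also fell, by 0.43 and 0.57, whereas Bmp2 and Bmp6 rose by 0.51 and 0.19, all named here after their values were seen. Among 24 genes of other growth factors and their receptors, 11 rose and 7 fell, the same as adjusted over the list alone. Figf, a vascular endothelial growth factor, rose by 1.52 and Fgfr2 by 1.11. Fgf7 fell 2.83-fold, and on the log2 scale Fgf2 fell by 1.48 and Pdgfc by 1.22. The medians were 0.27 and -0.02, and the adjusted p-values in camera were 0.697 and 0.906.

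No Wnt antagonist gene other than Dkk2 passed the threshold as lower. The list was dim, with a median signal of 3.76, and at a signal of 2 to 4 only 19.1% of all probes passed. Smaller falls could thus have been missed. Of 17 measured antagonist genes, 4 rose and only Dkk2 fell, also when adjusted over the list alone. The soluble frizzled-related gene Sfrp2 rose from 4.62 ± 0.07 to 6.49 ± 0.09 (SD, n = 3), or 3.64-fold, and Frzb rose by 1.27, Kremen2 by 0.47 and Dkk3 by 0.39. The list holds Dkk2, which the title of the series already names as lower, so it is not independent evidence of a direction. The adjusted p was 0.906. Among 19 Wnt ligand genes 5 rose and 3 fell, and among 27 receptors and transducers 6 rose and 5 fell, with equal counts adjusted over the list alone. Wnt8a rose by 2.24, Wnt10b by 2.05 and Wnt4 by 0.83, whereas Wnt8b fell by 1.78 and Wnt3a by 1.32. Wnt8a, Wnt10b and Wnt8b were near the lowest values in 1 genotype, and with the linear offset they differed by 1.30, 1.17 and -0.92. The receptor gene Ryk rose by 0.95 and Apc, part of the complex that degrades beta-catenin, by 1.49, whereas the dim gene Ror2 fell by 1.32, or 0.87 with the linear offset. The adjusted p-values were 0.697 and 0.929.

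Targets of beta-catenin moved in both directions. Of 20 measured, 5 rose and 7 fell, and adjusted over the list alone 5 rose and 8 fell. Axin2, a feedback inhibitor often used to read out the pathway, rose by 1.64 ± 0.22 (SE), and Wisp2 rose by 1.48. Axin2 was dim, with mean signals of 1.78 in wild-type and 3.42 in knockout cells, so the size of its rise is imprecise. Myc fell from 9.13 ± 0.07 to 7.44 ± 0.06 (SD, n = 3), or 3.23-fold, Fosl1 fell by 1.27 and the dim transcription factor gene Lef1 by 1.69, or 0.95 with the linear offset. The list median was -0.28, with an adjusted p of 0.213 in camera.

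Genes of actin and the contractile cytoskeleton moved in both directions. Of 27 measured, 14 rose and 9 fell, and adjusted over the list alone 15 rose and 9 fell. Smooth muscle myosin (Myh11) fell by 1.31 ± 0.10 (SE), calponin 1 (Cnn1) by 1.05, the tropomyosin gene Tpm2 by 0.93 and leiomodin (Lmod1) by 0.85. Cytoplasmic beta-actin (Actb) rose by 0.89 on its brighter probe, but its other probe differed by -0.03 with an adjusted p of 0.649. After quantile normalisation the brighter probe differed by 0.10 with an adjusted p of 0.115, and after cyclic loess by 0.53. That probe was at or near the highest value of its arrays. Quantile normalisation makes the highest values equal across arrays, so its small difference there cannot show whether Actb changed. The list had a median of 0.37 and a mean of -0.03, and an adjusted p of 0.931. After quantile normalisation and cyclic loess the median was 0.11, and the direction in camera turned from up to down. Only 2 of 13 septins in the list were measured, listed as clones for Sept12 and Sept14. Their differences were 0.40 and 1.08, with adjusted p-values of 0.363 and 0.113, and that list was too short to test.

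**Figure D2:**
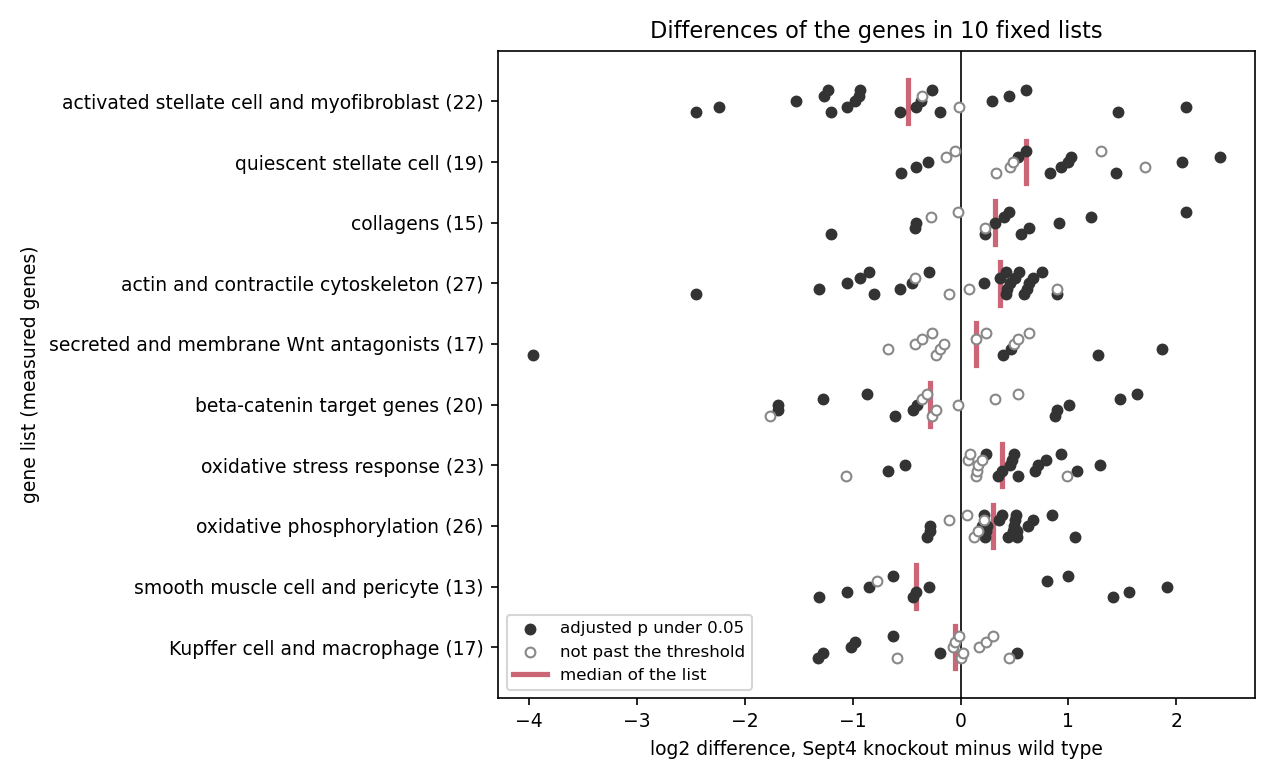
Log2 difference of each measured gene, knockout minus wild type (horizontal axis), in 10 of the lists (vertical axis, with the number of measured genes); filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians. The activated stellate cell list has a median of -0.49 and the quiescent list 0.61, and Dkk2 is the point near -4 among the Wnt antagonists.

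Genes of oxidative metabolism and of the oxidative stress response were mostly higher in the knockout. Of 26 genes of oxidative phosphorylation, 18 rose and 3 fell, and adjusted over the list alone 19 rose and 3 fell. The complex I subunit gene Ndufb8 rose by 1.06 ± 0.05 (SE), Ndufa1 by 0.85 and the complex II subunit gene Sdhb by 0.63. Of 23 oxidative stress genes, 13 rose and 2 fell, or 14 and 2 adjusted over the list alone. Haem oxygenase 1 (Hmox1) rose from 13.05 ± 0.05 to 14.35 ± 0.06 (SD, n = 3), or 2.46-fold, the glutathione transferase gene Gstm1 by 1.08, catalase (Cat) by 0.93 and Nqo1 by 0.72. Both lists passed in camera, with medians of 0.31 and 0.39 and an adjusted p of 0.0268 each. The calls were lost with adjusted p = 0.857 and adjusted p = 0.845 with an estimated correlation. They also ended after quantile normalisation, at adjusted p-values of 0.391 and 0.229, after cyclic loess, at 0.456 and 0.243, and without knockout replicate 3, at 0.0634 and 0.0741. Without the dimmest 25% of probes both stood at 0.0594, without the dimmest 50% at 0.177 and 0.155, and with the replicate number as a block both at 0.0542.

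The lists of secretory folding, glycolysis and cholesterol synthesis did not pass in camera. Of 23 genes of the unfolded protein response and secretory folding, 14 rose and 4 fell, the same as adjusted over the list alone. The transcription factor gene Xbp1 rose by 1.01 ± 0.05 (SE), the co-chaperone gene Dnajc3 by 0.86 and the chaperone BiP (Hspa5) by 0.75. The rise of Hspa5 shrank to 0.43 after quantile normalisation and after cyclic loess. Of 22 genes of glycolysis and hypoxia, 7 rose and 7 fell, and adjusted over the list alone 7 rose and 9 fell. Pfkl, a phosphofructokinase, fell by 1.67, the prolyl hydroxylase gene Egln3 by 0.76 and hexokinase 2 (Hk2) by 0.74. Of 17 cholesterol synthesis genes, 8 rose and 3 fell, again also adjusted over the list alone. Idi1 rose by 0.94 and squalene epoxidase (Sqle) by 0.81, whereas Cyp51 fell by 0.59. The medians were 0.34, -0.04 and 0.10, the last turning to -0.10 after quantile normalisation and -0.12 after cyclic loess. The adjusted p-values were 0.177, 0.419 and 0.906.

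Inflammatory mediators were divided between rises and falls. Of 29 chemokine, cytokine and NF-kappa-B target genes, 9 rose and 11 fell, and adjusted over the list alone 10 rose and 13 fell. Besides Ptgs2, interleukin 6 (Il6) fell by 1.30 ± 0.10 (SE), Ccl8 by 1.19, Cxcl5 by 1.15 and Cxcl14 by 1.11. Of 25 interferon response genes, 10 rose and 1 fell, also when adjusted over the list alone. Oas1a was the gene that fell, by 1.44, while the immunoproteasome subunit gene Psmb8 rose by 1.03 and Stat2 by 0.59. Of 22 immediate early genes, 4 rose and 6 fell, with the same counts adjusted over the list alone. Egr1 and Egr2 fell by 1.76 and 1.78, whereas Fosb rose by 1.27 and the dim nuclear receptor gene Nr4a3 by 2.53, or 1.55 with the linear offset. The medians were -0.06, 0.29 and -0.15, with adjusted p-values of 0.177, 0.419 and 0.128 in camera.

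Proliferation genes were more often higher than lower. Of 28 cell cycle genes, 15 rose and 3 fell, and adjusted over the list alone 16 rose and 4 fell. Nusap1 rose by 1.20 ± 0.05 (SE), the replication clamp gene Pcna by 1.14, Birc5 by 1.01 and the helicase subunit gene Mcm5 by 0.64. Ube2c, which serves the anaphase-promoting complex, fell by 1.74 and the mitotic kinesin gene Kif20a by 0.80. Of 23 apoptosis regulators, 7 rose and 5 fell, and adjusted over the list alone 7 rose and 6 fell. The death receptor gene Fas rose by 1.05 and Apaf1 by 0.58, whereas Bcl2 fell by 0.51. The medians were 0.23 and 0.07. The first fell to 0.09 after quantile normalisation and 0.07 after cyclic loess, and the second turned to -0.04 after either. The adjusted p-values were 0.128 and 0.906.

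Genes that neighbour Sept4 on chromosome 11 were tested as a list because passenger alleles can stay linked to a targeted locus. Of 22 measured, 9 rose and 2 fell, also when adjusted over the list alone. Cuedc1 rose from 4.99 ± 0.10 to 8.26 ± 0.10 (SD, n = 3), or 9.70-fold. The dim gene Bzrap1 rose by 1.90 with an adjusted p of 0.0478, which became 0.0636 after quantile normalisation, and with the linear offset it differed by 1.17. Ypel2 rose by 0.66, and the phosphatase gene Mtmr4 fell by 0.72. The list median was 0.30, with an adjusted p of 0.620.

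Markers of other liver cells were measured to describe what else the samples could hold, and none of the 11 marker lists passed in camera. Of 17 Kupffer cell and macrophage genes, 1 rose and 6 fell. The complement genes C1qa, C1qb and C1qc fell by 0.98, 0.63 and 1.32, and Emr1, which encodes a macrophage surface receptor, fell by 1.27, whereas the Kupffer cell lectin gene Clec4f rose by 0.52. Of 13 smooth muscle and pericyte genes, 5 rose and 7 fell. The channel genes Kcnj8 and Abcc9 rose by 1.92 and 1.57 and Notch3 by 1.41, while Myh11 and Cnn1 fell. Of 18 hepatocyte genes, 6 rose and 2 fell, with albumin (Alb1) up by 0.88 and transthyretin (Ttr) down, at -0.42. Of 16 endothelial genes, 6 rose and 2 fell, with Fcgr2b up by 1.13, Stab1 up by 0.73 and Flt1 down, at -0.86. Of 14 portal fibroblast and mesothelial genes, 2 rose and 4 fell, among them Thy1 and Upk1b, the latter at -1.23. These counts were the same adjusted over the list alone. The adjusted p-values, in the order given, were 0.143, 0.545, 0.681, 0.906 and 0.128.

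Most lists of markers of leukocytes, bile duct cells and blood held both rises and falls. By comparison, 44.2% of all probes with 1 symbol passed. Of 13 neutrophil genes, 2 rose and 4 fell, including Mmp8 and Ly6g, which fell by 0.48. Of 11 dendritic cell and MHC class II genes, 4 rose and 2 fell, with Itgax up by 1.01 and Cd74 down, at -1.13. Of 9 cholangiocyte and progenitor genes, 1 rose and 3 fell, among them Cldn4 at -0.60, and the list median of 0.06 turned to -0.01 after cyclic loess. Of 9 erythroid and platelet genes, only the platelet factor gene Cxcl4 passed, higher by 0.41. These counts were also those adjusted over the list alone. Of 15 T and NK cell genes, 1 rose and 3 fell, with Thy1, shared with fibroblasts, the largest fall, and adjusted over the list alone 1 rose and 1 fell. Of 12 B and plasma cell genes, Cd22 rose by 0.25 and Sdc1 fell by 0.36, and adjusted over the list alone only the fall remained. The adjusted p-values, in the order given, were 0.245, 0.906, 0.407, 0.906, 0.620 and 0.942.

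In all, 35 of the 36 lists could be tested and 3 passed in camera at the preset correlation, namely the activated stellate cell, oxidative phosphorylation and oxidative stress lists. With an estimated correlation limma's camera called 0, and 0 had an unadjusted p under 0.05. The median, the mean and the direction in camera differed in sign for the lists of matrix proteases, Wnt ligands, Wnt receptors, Wnt antagonists, actin, T and NK cells, B cells, cholangiocytes and smooth muscle. The direction in camera turned after both scalings for the lists of Wnt receptors, Wnt antagonists, actin, apoptosis and B cells. After quantile normalisation the activated and quiescent stellate cell medians were -0.76 and 0.44, those of oxidative phosphorylation, oxidative stress and secretory folding 0.15, 0.21 and 0.23, and those of transforming growth factor beta and interferon genes 0.12 and 0.15. Those of non-collagen matrix, chemokines, glycolysis, immediate early and Kupffer cell genes were -0.15, -0.20, -0.18, -0.25 and -0.15, and those of growth factors, Wnt receptors, retinoid, T and B cell genes -0.07, 0.06, 0.08, 0.21 and 0.13. Camera sets a list against the other genes, whose median difference was 0.14.

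**Figure D3:**
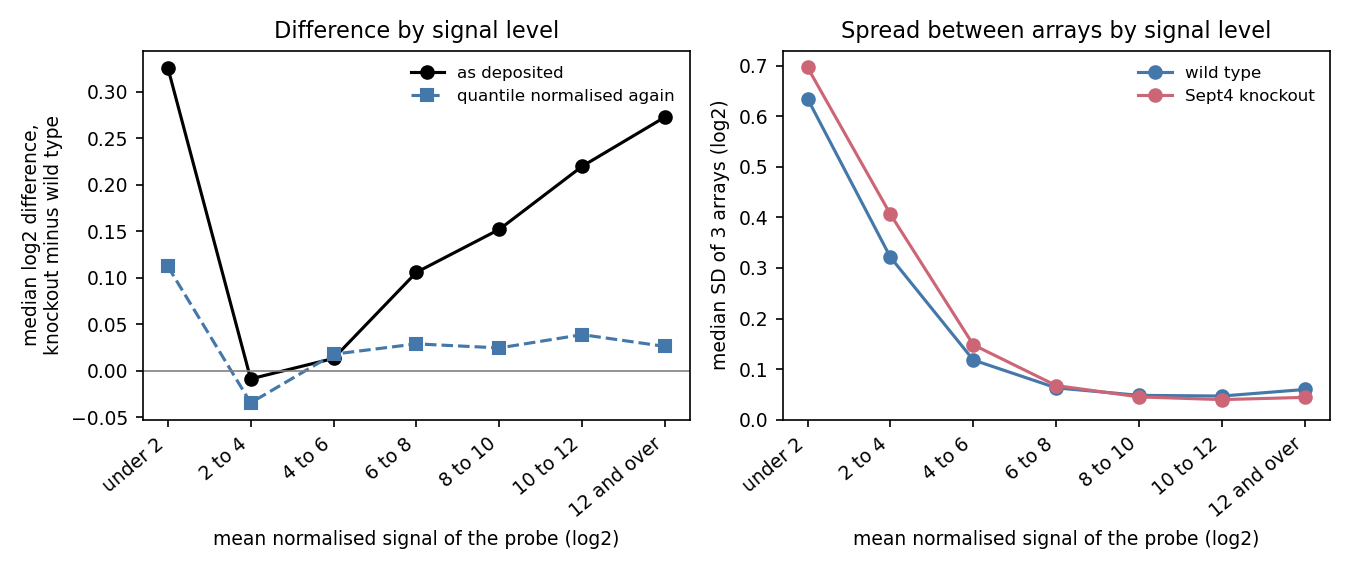
Median log2 difference, knockout minus wild type (left), and median SD of the 3 arrays of each genotype (right), for probes grouped by their mean log2 signal (horizontal axes). As deposited, the median difference is 0.33 under a signal of 2, 0.01 at 4 to 6 and 0.27 at 12 and over, where quantile normalisation gives 0.11, 0.02 and 0.03, and the median SD falls from 0.64 and 0.70 under a signal of 2 to 0.06 and 0.04.

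The spread between arrays depended on signal. Under a log2 signal of 2 the median SD was 0.64 in wild-type and 0.70 in knockout arrays, and 12.7% of 4161 probes passed. At a signal of 8 to 10 the median SD was 0.05 and 0.04, and 69.3% of 3120 probes passed.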

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

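Cyclic loess and the removal of probes at an array's lowest value were chosen after the data were seen; the other alternatives were planned. The number of probes past the threshold stayed within 1.5 times of 10025 under every alternative run, from 7724 to 11792. After quantile normalisation, 8880 of the 10025 calls passed again with the same sign. Of the 10025, 69 changed sign, whether or not they passed again. Dkk2 passed in all 15 alternatives that gave it a value, with differences of -4.12 to -2.86 and adjusted p-values of 2.23e-12 to 0.0189; leaving out the dimmest 50% of probes, or those at an array's lowest value, removes its probe. Of 201 named genes past the threshold, counted once per gene, 165 stayed past it in every alternative with a value, and none changed sign. Sept4 has no value under any setting.

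The number of probes at least 2-fold apart at an unadjusted p under 0.05, 2006, fell to 1053 without the dimmest 25% of probes, 482 without the dimmest 50% and 1139 with the linear offset, because fewer or compressed dim probes were tested. The number of lists called, 3, became 1 after quantile normalisation, after cyclic loess, without the dimmest 25% of probes and without knockout replicate 3. Leaving out each array gave 1 to 3 lists. Without the dimmest 50% of probes, 2 were called, both lower: the activated stellate cell list and the immediate early genes, at an adjusted p of 0.0407. It was 5 with the trended and robust prior, 0 with an estimated correlation and 29 with fry, which asks only whether a list's genes move, on balance, one way. Beyond the construction of fry and the estimated correlation, the cause was not tested. The activated stellate cell list was called under every alternative except the estimated correlation, and wherever 1 list was called it was that one. Of the lists called by fry but not by camera, 4 took the other direction, at unchanged medians: growth factors (-0.017), Wnt receptors (0.0894), Wnt antagonists (0.14) and smooth muscle (-0.41).

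The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.00775, -0.00135 and -0.00196. With the replicate block, 7724 probes and 1 list were called.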

Other observations

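The 14 gene families described first, the windows around Sept4, the smooth muscle test and the test of genes near Sept4 were chosen after the data were seen; the brightness tests were chosen once the effect of normalisation on the lists was known, before their percentiles were.

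Several families outside the fixed lists held strong changes without moving as a group. Of 59 cytochrome P450 genes, 18 rose and 4 fell. Cyp11a1, the first enzyme of steroid synthesis, rose by 2.26 ± 0.13 (SE) and Cyp1a2 by 1.56, whereas Cyp1b1 fell by 1.52 ± 0.06 (SE). Of 19 glutathione transferase genes, 10 rose and 3 fell, with Gstm3 up by 1.47. Of 12 tubulin genes, 7 rose and 2 fell, Tubb3 by 1.49 and Tubb2b at -1.39. Of 39 serpins, 11 rose and 9 fell, Serpina3g by 2.53 and Serpinb2, which inhibits plasminogen activators, at -1.69. Of 20 semaphorins, 6 rose and 3 fell, and the secreted guidance cues Sema3c and Sema3e fell by 1.33 and 1.21. Of 23 integrins, 6 rose and 3 fell, Itga8 by 1.17 and Itga4 at -1.15.

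Of 55 cytosolic ribosomal protein genes 27 rose and 10 fell, of 74 mitochondrial ones 28 and 14, and of 36 proteasome subunits 19 and 7, but for these 3 families the direction in camera turned under both quantile normalisation and cyclic loess. Of 20 heat shock genes 10 rose and 2 fell, with Hsp90ab1 at -1.20, and of 20 histone genes 7 rose and 4 fell. Among 663 olfactory receptors 77 rose and 75 fell, among 35 protocadherins 4 and 5, and among 10 keratins 1 and 1. The olfactory receptors were dim, with a median signal of 2.31, yet 54 of the 663 passed with at least a 2-fold difference. By comparison, 6.43% of all probes with 1 symbol did so. A large difference on a dim probe was thus common, and whether such calls reflect expression was not tested. None of the 14 families passed in camera, where the smallest adjusted p was 0.441 at the preset correlation and 0.0869 with an estimated one.

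The oxidative phosphorylation and oxidative stress lists were higher in the knockout, and above a signal of 4 the median difference of all probes grew with signal, from 0.01 at 4 to 6 to 0.27 at 12 and over. It was largest under a signal of 2, at 0.33, so the trend does not hold over the whole range. The lowest values of the arrays also differed, at 0, 0.12 and 0.22 in wild type and 0.32, 0.31 and 0.32 in the knockout. After quantile normalisation the median difference under a signal of 2 was 0.11. Against 10000 random lists matched on brightness, the 2 list medians lay at percentiles 67 and 92.8, inside the central 95%. A candidate explanation, for the range above 4, is that brighter probes are higher in the knockout arrays whatever the gene. Whether that trend comes from scaling or from the genotypes was not tested. On the same measure the secretory folding list lay at 84.2 and the cell cycle list at 68.6.

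The lower activated stellate cell list is not explained by brightness: if brighter probes differ between the groups whatever the gene, matched lists should reach its median of -0.49, and 0 of 10000 did. The central 95% of matched medians ran from 0.00 to 0.43. Fewer smooth muscle cells and pericytes in the knockout samples could lower Tagln, Myh11 and Cnn1, but 5 of the 12 markers of those cells past the threshold were higher, Kcnj8 and Abcc9 among them. Stellate cells express several of these markers, which keeps this explanation open. The quiescent stellate cell median, 0.61, lay above all 10000 matched lists, at 100. Matched genes were drawn independently, so these lists lack any correlation between markers of 1 cell type, and the percentiles are not list tests. In camera the quiescent list had an adjusted p of 0.128 at the preset correlation. With an estimated correlation both stellate cell lists had an adjusted p of 0.752.

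Cuedc1, the 15th named gene from Sept4 on chromosome 11, was among the largest rises. If many genes around Sept4 changed together, the list of neighbours should hold more 2-fold changes than matched lists, but it held 2 of 22, no more than the upper limit of 4 of the central 95% of those lists. In windows of 5, 10, 25 and 50 named genes on each side, 1, 1, 3 and 4 genes were at least 2-fold apart, against 6.40% of all placed genes. Fisher's exact test gave p-values of 0.484, 1, 1 and 0.415, adjusted over the 4 windows to 0.968, 1, 1 and 0.968. An effect of the targeted allele on Cuedc1 alone was not tested.

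The 6 arrays can be split into 3 and 3 in 10 ways, and in each case 1 of the 10 splits, the real one, gave a result as large. It gave 10025 probes past the threshold, where the highest other gave 0, 2006 probes at least 2-fold apart, where the highest other gave 377, and 3 lists, where the highest other gave 0. So few splits cannot give a share under 0.05.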
